A study of Mus musculus with 12 samples.

How the data were processed

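Gene expression was measured on Affymetrix arrays with biotin-labelled cRNA from whole uteri of mice of 2 genotypes. Mice carrying floxed SRC-2 alleles without Cre are called wild type here, as in the labels. Mice that also carried Cre recombinase at the progesterone receptor locus are called mutant. All had been ovariectomized and later received vehicle (sesame oil) or progesterone (P4), and RNA of 3 mice was pooled for each array. The deposited values are 1 linear intensity per probe set and array, as made by the authors. The labels give the labelling protocol, but the sources used here do not name the software that summarised the probes or the normalization between arrays, so both are unknown. No detection calls were available.

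Groups were taken from the sample titles, source names and genotype fields, which give the same groups. The free-text description of all 12 arrays names wild-type vehicle pools and was not used. The array medians on the log2 scale lay within 0.066 of each other, so the deposited scaling was kept. Intensities became log2(intensity + 16). Of 45101 probe sets, 64 controls, 932 that name several genes and 9211 without a gene name here were left out of the gene tests. Each gene was represented by its probe set of highest mean, which gave 18193 genes. The 4548 genes under the 25th percentile of the mean log2 value (log2 5.21, an intensity of 21.1) were left out, and 13645 genes were tested. A RefSeq gene table was used for gene names and for the order of genes on their chromosome only. Its gene IDs matched 34754 named probe sets and changed 0 symbols.

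Group means were fitted over the 12 arrays with limma 3.58.1 in R 4.3.3, and 5 contrasts were tested with its moderated test. These were P4 minus vehicle in each genotype, mutant minus wild type in each treatment, and the difference between the P4 responses (the interaction). P values were adjusted by Benjamini-Hochberg over all genes tested, and genes were called at an adjusted p under 0.05. Standard errors (SE) are those of the fit. Ratios given as times higher or lower are 2 to the power of the log2 difference, so the added 16 makes them smaller than ratios of raw intensities for dim genes. The 24 gene lists were tested with limma's camera (preset correlation 0.01, two-sided), adjusted over 120 tests (24 lists by 5 contrasts). The same test with the correlation estimated for each list, and limma's fry, stand beside it. Of 463 distinct listed genes, 35 were not named on the array, 402 were tested and 21 of those stood in more than 1 list. The size of the P4 response was compared between genotypes by an exact permutation test over 400 assignments of the genotype labels within treatments, two-sided. Its genes were chosen on treatment alone. Tables were plotted with Python 3.11.15 and matplotlib 3.10.9.

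Lists, tests and the rule for named genes were set before the data were examined. The rule named Ncoa2 and Pgr, then for each contrast up to 10 genes with the largest rise and up to 10 with the largest fall. These had to be called and, except for the interaction, to have groups that did not overlap. Up to 4 called members of each list and contrast with the smallest adjusted p were named as well, and uncalled members where a list is described. Clones and predicted genes were counted without a name.

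The methods were tested on simulated data of 13645 genes with 200 changed, in 5 runs. P4 in wild type recovered 64.5% of changes of 0.5 on the log2 scale, 92.5% of changes of 1 and 99.4% of changes of 2, and 4.04% of its calls were false. The interaction recovered 35.8%, 84.8% and 98.5%, and 4.83% of its calls were false. The response test was tried on a separate simulation of 13645 genes with 1000 changed by 1 on the log2 scale in wild type. In 5 runs with equal responses it gave medians of -0.0101 to 0.00452 and exact permutation p values of 0.065 to 0.815. In 5 runs with a mutant response of 0.7 of the wild-type one (true difference -0.3), the response test gave medians of -0.3 to -0.276 and exact permutation p values of 0.01 to 0.095, so it can miss such a difference. Simulated genes varied independently, whereas many genes in the real pools varied together. These rates and medians may therefore not carry over to the real pools.

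The number of arrays (3 per group) limits the precision of every value. Replicate numbers were checked for pairing. Of 18 pairs of pools that share a number across groups, 4 had residuals correlated over 0.1 (range -0.191 to 0.271), and 3 of 12 pools correlated best with a pool of their own number, so no pairing was modelled. The alternatives tried were other normalizations (quantile, median centring), added constants of 1 and 64, other filters on dim genes, each probe set on its own, the mean of a gene's probe sets, and fits of only the compared groups. Others were a replicate block, a trended robust prior, array weights, stricter thresholds, other list tests and leaving out each pool. The mean of the adipocyte list as a covariate was added after the data had been seen.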

Results

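Uterine expression was measured in 12 pools, each of 3 mice and hybridized to 1 array. There were 3 pools for each combination of genotype (wild type or SRC-2 mutant) and treatment (vehicle or 1 mg of P4), from 36 mice in all. The mice had been ovariectomized at 6 weeks of age and rested for 2 weeks, and uteri were taken 6 h after treatment. SRC-2, encoded by Ncoa2, is a coactivator of steroid receptors, and Cre in the mutants came from the locus of Pgr, the progesterone receptor gene. The wild-type mice carried no Cre. In every comparison of genotypes, an effect of Cre or of its insertion at Pgr cannot be told apart from SRC-2 loss. The median intensity per array ran from 44.6 (mutant vehicle pool 1) to 47.5 (wild-type vehicle pool 3). Pools of the same group correlated at 0.989 to 0.994 across genes (12 pairs), and pools of different groups at 0.962 to 0.992 (54 pairs). Genes are not independent replicates. The first principal component held 55.3% of the variance and set all P4 pools apart from all vehicle pools.

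The first comparison asked whether the mutants had less Ncoa2 transcript. The intensity of Ncoa2 was 1375 ± 52.5 (SD, n = 3) in wild-type vehicle pools and 593.7 ± 26.9 in mutant vehicle pools, 2.28 times lower (log2 difference -1.19, SE 0.0709, adjusted p = 3.28e-05). With P4 it was 970.5 ± 77.5 in wild type and 472.8 ± 18.2 in mutants, 2.02 times lower (adjusted p = 6.69e-05). All 3 mutant pools lay below all 3 wild-type pools under both treatments. Ncoa2 also fell with P4, by a log2 change of -0.50 in wild type (adjusted p = 0.000275) and -0.32 in mutants (adjusted p = 0.00712), and these responses did not differ by the test (interaction 0.18, adjusted p = 0.487). Pgr had an intensity of 3407 ± 413 in wild-type vehicle pools and 2955 ± 186 in mutant vehicle pools, a difference that was not called (log2 -0.20, SE 0.0862, adjusted p = 0.469). P4 lowered Pgr to 1890 ± 60.7 in wild type (log2 change -0.84, adjusted p = 3.05e-05) and to 1979 ± 91.4 in mutants (-0.57, adjusted p = 0.000825). The 2 dimmer Pgr probe sets, tested on their own, were called with P4 in wild type (-0.91 and -0.44). In mutants they were not called (-0.51, limma adjusted p = 0.106, and -0.09, limma adjusted p = 0.587). Both lay lower in mutant than in wild-type vehicle pools without a call (-0.36 and -0.30). Where the Ncoa2 probes lie relative to the deleted part of the gene is not given, so the remaining signal does not measure how complete the deletion was. A dimmer Ncoa2 probe set lay lower in the mutants as well, at 89.81 against 47.37 with vehicle and 68.43 against 24.51 with P4 (wild type first), though tested on its own it was called with P4 (adjusted p = 0.0022) and not with vehicle (0.0798). The remaining 2 Ncoa2 probe sets had mean intensities of 39.82 or less in all groups and no called difference. With the mean of all Ncoa2 probe sets the vehicle difference was -0.45 and was not called (adjusted p = 0.0526).

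**Figure D1:**
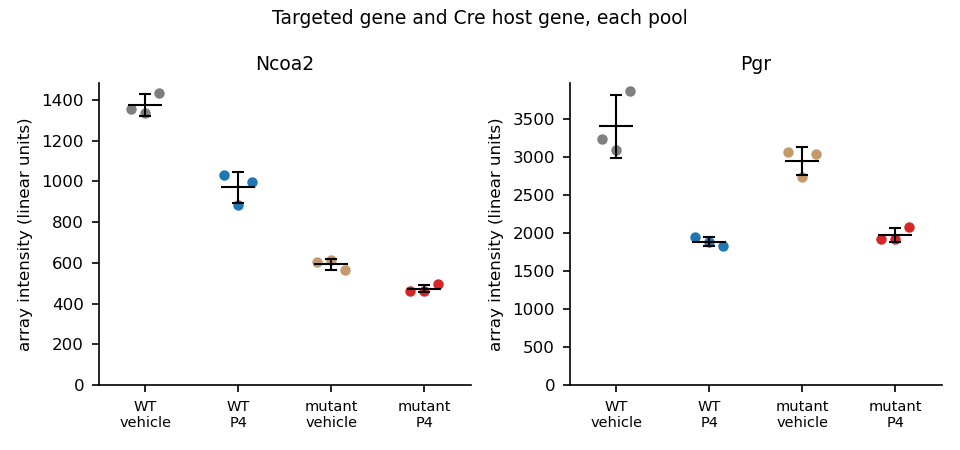
Array intensity (linear units) of Ncoa2 and Pgr in each pool, by group; dots are pools, the horizontal mark is the mean and the bars are the SD (n = 3). Ncoa2 is 2.28 times lower in mutant than in wild-type vehicle pools, and Pgr is lower with P4 in both genotypes.

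P4 in wild-type uteri changed a large part of the measured transcripts within 6 h. The largest rises were in Slc6a14, an amino acid transporter gene (18.8 times higher, adjusted p = 4.54e-08), Sprr2d (13.7), Acod1, which makes itaconate (13.1), Adh6a (12.6), Fam107a (11.0) and Npl (9.71). Acot7 (8.82), the mitochondrial folate enzyme gene Mthfd2 (8.61), the receptor co-chaperone gene Fkbp5 (8.18) and Cyp26a1, whose product degrades retinoic acid (7.63), also rose. The largest falls were in Gabrp (6.85 times lower), the epithelial Wnt ligand gene Wnt7a (6.71), Cdkl1 (6.15) and the retinoid transporter gene Abca4 (4.95). Mmp12 (4.36), Ctnnd2 (4.29), Sv2b (4.29), Pik3ip1 (4.18), Rassf10 (4.07) and Klhl14 (3.97) also fell. In limma, 5111 of 13645 genes were called, 2314 higher and 2797 lower, and 238 of the higher and 158 of the lower genes differed at least 2-fold. Groups did not overlap for 6856 genes (50.2%, against 10% by chance). The other bright probe set of Wnt7a went the opposite way without a call. Mmp12 was no longer called without wild-type vehicle pool 2 or 3 or wild-type P4 pool 2 or 3.

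Genes known to be induced by P4 in the uterus rose as a group. Of 23 tested members, 17 rose and 1 fell (17 and 2 adjusted over the list alone), with a median log2 change of 0.894 (camera adjusted p = 4.68e-08, and adjusted p = 0.149 with an estimated correlation). Among them were Ihh, the hedgehog ligand gene of the epithelium (3.93 times higher), Hsd11b2, whose product inactivates glucocorticoids (5.89), and Il13ra2 (6.46). Genes shared with the glucocorticoid response rose too, 13 of 20 with 1 fall (13 and 1 over the list alone), at a median of 0.617 (camera adjusted p = 8.01e-07, adjusted p = 0.272 with an estimated correlation). They included the kinase gene Sgk1 (4.76 times higher) and the metallothionein genes Mt2 (2.75) and Mt1 (2.53). Of 29 cell cycle genes, 10 rose and 2 fell (12 and 2 over the list alone), at a median of 0.426 (camera adjusted p = 0.00551, adjusted p = 0.826 with an estimated correlation). Top2a, Birc5 and Aurka, which act in mitosis, rose by log2 changes of 1.24, 0.89 and 0.62, while Mcm7, a replication helicase gene, changed by -0.35. The other bright probe set of Top2a had the opposite sign, uncalled. Without wild-type vehicle pool 2 Birc5 was no longer called, nor was Aurka without wild-type P4 pool 2. Endothelial markers fell, 7 of 17 and none higher (10 fell over the list alone), at a median of -0.257 (camera adjusted p = 0.0125, adjusted p = 0.736 with an estimated correlation). Cldn5, Robo4, Erg and Tie1 had log2 changes of -0.95, -0.50, -0.44 and -0.31.

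The other lists were not called by camera in wild type, though many held called genes that went both ways. Counts adjusted over the list alone are given where they differed. Of 21 glycolysis genes 9 rose and 5 fell (6 fell over the list alone; camera adjusted p = 0.101), and Pfkfb3, which makes an activator of glycolysis, rose 4.72 times, the glucose transporter gene Slc2a3 4.01 times and Hk2 3.17 times. Of 26 Wnt pathway genes 2 rose and 10 fell (0.0986), with Wnt11 at 1.74, Fzd10 at -1.12 and the stem cell marker Lgr5 at -1.49. Of 17 circadian clock genes 6 rose and 8 fell (0.997), among them Nfil3 (2.05), Npas2 (1.71) and Rora (-0.99). Immediate early genes rose in 8 and fell in 3 of 23 (0.084), BMP and TGF-beta genes rose in 2 and fell in 8 of 23 (9 over the list alone, 0.108), with the activin-binding Fst at 1.90 and Bmp4 at -0.69. Estrogen-responsive genes rose in 6 and fell in 4 of 20 (0.621), with Greb1 at 1.52 and Igf1 at 1.40. Steroid receptors and coregulators rose in 5 and fell in 8 of 17 (0.423), Hox and Mullerian genes rose in 3 and fell in 5 of 15 (4 rose over the list alone, 0.88), with Hoxa10 at 0.89 and Hoxa11 at 0.75. Hedgehog axis genes rose in 3 and fell in 1 of 13 (3 fell over the list alone, 0.521), and EGF family genes rose in 2 and fell in 3 of 9 (0.93). Ion and water transport genes rose in 7 and fell in 2 of 18 (0.423), and cholesterol synthesis genes rose in 5 and fell in 2 of 18 (0.397). Among cell type markers, leukocyte genes rose in 3 of 29 (2 over the list alone, 0.0986), with the neutrophil genes S100a8 and S100a9 6.97 and 6.72 times higher. Epithelial markers rose in 1 and fell in 5 of 20 (0.617), stromal markers rose in 1 and fell in 2 of 17 (0.872), and interferon genes fell in 3 of 19 (0 over the list alone, 0.617). Smooth muscle markers fell in 1 of 16 (0.834), oviduct and ovary markers fell in 1 of 6 (0.872), and adipocyte markers (0 of 8, 0.853) and red blood cell markers (0 of 2, 0.79) held no call. Median, mean and test differed in sign for the circadian, smooth muscle and EGF lists.

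P4 in mutant uteri changed many of the same genes. Acod1 (13.4 times higher), Slc6a14 (11.5) and Npl (10.6) rose most, followed by Cwh43 (5.71), Adh6a (5.49), Fam107a (5.47), Mthfd2 (5.36), the chemokine gene Ccl28 (5.27), the endocytic receptor gene Lrp2 (4.87) and Acot7 (4.82). The largest falls were in Pck1, a gluconeogenesis enzyme gene (5.56 times lower), Ctnnd2 (5.40), Gabrp (5.04), Mycn (4.6), Wnt7a (4.08), the lipid droplet gene Cidec (3.84), Lrrtm1 (3.81), Cdkl1 (3.75), the fatty acid carrier gene Cd36 (3.66) and Orm1 (3.55). Pck1, Cd36, Orm1 and Cidec, itself in the adipocyte list, lost these calls with the mean of that list as a covariate. In limma, 3807 genes were called, 1621 higher and 2186 lower, with 109 in each direction at least 2-fold, and groups did not overlap for 5757 genes (42.2%, against 10% by chance). Of the genes higher in mutants, 1272 were also higher in wild type, against 274.9 for independent calls, and of the lower genes 1610, against 448.1. Calls in opposite directions numbered 8 and 5.

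In the mutants too, the progesterone-induced list rose, 15 of 23 with 0 falls (15 and 2 over the list alone), at a median of 0.608 (camera adjusted p = 5.16e-07, adjusted p = 0.149 with an estimated correlation), with Ihh 4.68, Hsd11b2 4.75, Fkbp5 3.10 and Gata2 1.52 times higher. The glucocorticoid-shared list rose in 7 of 20 with 1 fall (8 and 1 over the list alone), at a median of 0.184 (camera adjusted p = 0.000576, adjusted p = 0.345 with an estimated correlation), with Sgk1 4.67, Mt2 2.67 and Mt1 2.36 times higher. Endothelial markers fell in 7 of 17 (8 over the list alone), at a median of -0.23 (camera adjusted p = 0.0117, adjusted p = 0.736 with an estimated correlation), among them Cldn5 (-0.69) and Pecam1 (-0.59), and this list was no longer called without mutant P4 pool 1. The cell cycle list was not called (median -0.0884, camera adjusted p = 0.602), and its 4 called members, the replication helicase genes Mcm6, Mcm7, Mcm5 and Mcm3, had log2 changes of -0.69, -0.48, -0.50 and -0.47. Adipocyte markers fell in 4 of 8 (8 over the list alone), at a median of -1.5 (camera adjusted p = 0.0125, adjusted p = 0.753 with an estimated correlation), with Lep at -1.57, Pparg at -1.31, Cidec at -1.94 and Lpl at -1.22. That list was no longer called without mutant vehicle pool 2. With the mean of the adipocyte list as a covariate, an alternative added after the data had been seen, 1612 genes were called in mutants, 1553 of them shared with the 3807. Log2 changes shrank from -2.47 to -0.60 for Pck1, from -1.87 to -0.39 for Cd36 and from -1.83 to -0.50 for Orm1, and these calls ended. That of Acod1 ended at a change of 4.14 against 3.74, as its SE rose from 0.879 to 1.23. The median SE rose from 0.0929 to 0.127 and 3806 of the 3807 genes kept their direction.

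The next comparison asked how the genotypes differed without hormone. Mutant vehicle pools had less transcript of the keratin genes Krt5 (17.2 times lower on the scale used), Krt13 (6.63) and Krt15 (5.24), which mark stratified epithelia, and of Trp63, the transcription factor gene of basal cells (2.36). Ncoa2, Abca4 (2.02 times lower), Gkn3 (1.94), Tfap2a (1.65) and Slc16a9 (1.41) were lower as well. Lgi1 (2.04 times higher), Bmp5 (2.00), the aldehyde dehydrogenase genes Aldh1a7 (1.99) and Aldh1a1 (1.70), Cfap300 (1.5) and Acbd7 (1.33) were higher. Krt5 had an intensity of 531.4 ± 13.6 (SD, n = 3) in wild-type and 16.26 ± 6.2 in mutant vehicle pools. This level, like those of Krt13 in mutant vehicle pools (10.46 to 11.57), lay under the dim filter of 21.1, so the ratios of both genes are set by the added 16 and the floor, and their exact sizes and order carry no weight. In the wild-type P4 pools it spread from 29.7 to 560.8, and Krt14, named after its values were seen, spread from 54.76 to 600.0. With limma, 16 of 13645 genes were called, 6 higher and 10 lower (1 of them a Riken clone), 1353 passed an unadjusted p of 0.05, and 2226 had groups that did not overlap (16.3%, against 10% by chance). The count was 39 without wild-type P4 pool 2, and 2 to 7 without any other 1 pool except wild-type P4 pool 3. Ncoa2 and Aldh1a7 alone held their calls in all 12 fits that left out 1 pool. With the adipocyte covariate 19 genes were called, 3 higher and 16 lower, and only 9 of the first 16 were among them. All 16 kept their direction, and the median SE rose from 0.0929 to 0.131.

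No member of the cell cycle list was called over all genes in vehicle pools, but 28 of 29 were higher in mutants and 20 were called adjusted over the list alone. The median log2 difference was 0.515 (camera adjusted p = 2.11e-15, adjusted p = 0.35 with an estimated correlation). Tk1, Birc5, Top2a and Mki67 had differences of 0.86, 0.83, 0.77 and 0.74. All 8 adipocyte markers were higher, 8 over the list alone and 0 over all genes, at a median of 1.49 (camera adjusted p = 6.64e-08, adjusted p = 0.345 with an estimated correlation), with Retn at 2.49 and Adipoq at 1.80. The mean log2 value of the adipocyte list per pool was 8.78 ± 0.595 in wild-type vehicle, 8.87 ± 0.844 in wild-type P4, 10.4 ± 0.739 in mutant vehicle and 8.89 ± 0.646 in mutant P4 pools (SD, n = 3). That of the cell cycle list was 7.12 ± 0.182, 7.51 ± 0.189, 7.59 ± 0.134 and 7.54 ± 0.288 in the same order. Leukocyte markers were higher in 23 of 29, with 0 called over all genes and over the list alone (median 0.149, camera adjusted p = 0.0986). Interferon genes were called higher by camera (19 of 19 positive, 0 called, median 0.335, adjusted p = 0.000825, and 0.753 as the adjusted p with an estimated correlation), with Oas1a at 0.55 and Ifit1 at 0.46. Epithelial markers were higher at a median of 0.16 (0 called, adjusted p = 0.00167, and adjusted p = 0.705 with an estimated correlation). The hedgehog axis (median -0.129, adjusted p = 0.0109), immediate early genes (-0.0878, 0.0117), steroid receptors (-0.0616, 0.0162, Ncoa2 the 1 call) and circadian genes (-0.0845, 0.0356) were lower, and their adjusted p values with an estimated correlation were 0.333, 0.345, 0.35 and 0.35. The epithelial list was no longer called without mutant vehicle pool 1, the immediate early list without mutant vehicle pool 2 and the steroid receptor list without wild-type vehicle pool 1 or mutant vehicle pool 3. The circadian list lost its call without wild-type vehicle pool 1 or 2 or mutant vehicle pool 2 or 3. The adipocyte covariate ended those of the hedgehog, epithelial, immediate early and interferon lists, whose medians moved to -0.0836, 0.094, -0.0664 and 0.188. Median SEs of members rose from 0.0953 to 0.135, 0.145 to 0.203, 0.108 to 0.15 and 0.246 to 0.343, so both a smaller difference and lower precision enter the losses. It added calls of the glucocorticoid-shared (median 0.15, camera adjusted p = 0.00852) and ion and water transport lists (-0.172, 0.0331). Both rest on the preset correlation, and an estimated one was not tried with the covariate. Without the covariate their camera adjusted p values with an estimated correlation were 0.85 and 0.35. Median and mean differed in sign for the estrogen and Hox lists, which were not called (0.775 and 0.872).

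**Figure D2:**
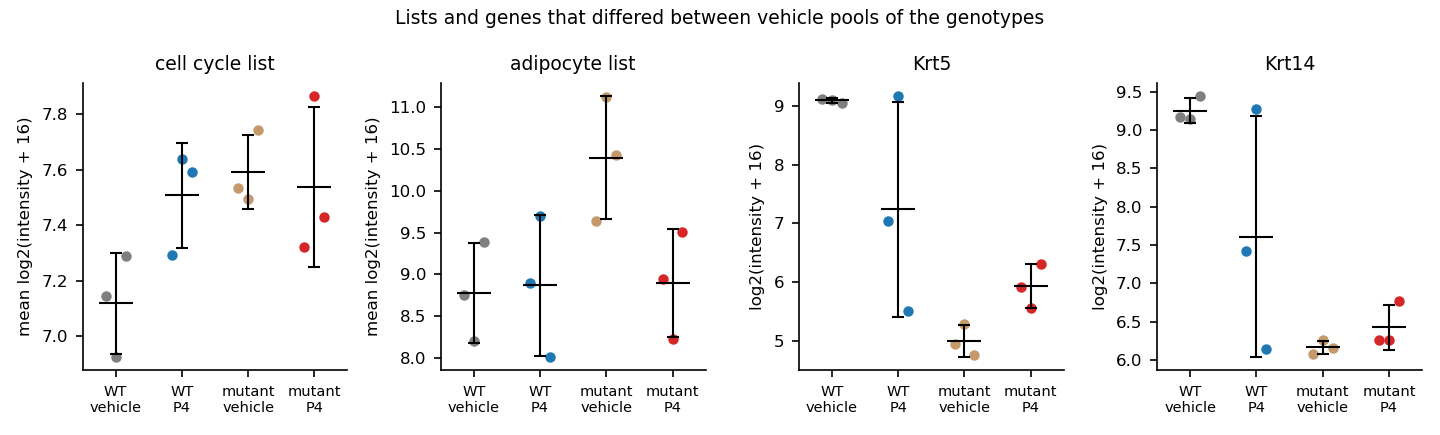
Mean log2(intensity + 16) of the cell cycle and adipocyte lists and log2(intensity + 16) of Krt5 and Krt14 in each pool, by group; dots are pools, the horizontal mark is the mean and the bars are the SD (n = 3). Both lists are higher in mutant than in wild-type vehicle pools, and Krt5 and Krt14 are lower there, with wild-type P4 pools spread widely.

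The genotypes were also compared after P4. Atp6v0d2, a proton pump subunit gene, was 5.34 times lower in mutant P4 pools (adjusted p = 6.69e-05), Cyp26a1 4.05, Fst 3.59, the interleukin 13 decoy receptor gene Il13ra2 3.11 and the tight junction gene Cldn2 2.69 times lower. Wfdc15b (2.34), Scube2 (2.32), the neurokinin gene Tac2 (2.30), Ttr (2.27) and Fkbp5 (2.20) were also lower. P4 had raised each of these named genes in wild type, a comparison that shares the wild-type P4 pools with this one. Wnt7a, which P4 lowered in both genotypes, was 2.62 times higher in mutants, and Ppp1r36 (2.12), Cdkl1 (1.82), Tspan8 (1.75), Acpp (1.63), the Wnt deacylase gene Notum (1.60), Pik3ip1 (1.59), Fzd10os (1.59) and Kctd14 (1.58) were higher as well. Wnt7a also lay higher in every mutant vehicle pool (log2 9.15 to 9.40) than in every wild-type one (8.51 to 8.68), without a call. Its interaction was not called, so a weaker fall with P4 in mutants was not shown. In limma 187 genes were called, 53 higher and 134 lower in mutants, with 2 and 14 at least 2-fold. Groups did not overlap for 2683 genes (19.7%, against 10% by chance). For Wnt7a the other bright probe set again had the opposite sign in mutants, both with P4 against vehicle and against wild type, without a call. Of 116 calls of named genes that have other bright probe sets, these all had the same sign in 102, and 0 had a call in the opposite direction. The single other bright probe set of Npas2 and Nr4a3 with P4 in wild type, of Smad3 with P4 in mutants and of Trp63 between vehicle pools also had the opposite sign. Ncoa2, Cfap300 and Trp63 were called in the same direction under both treatments, 3 genes against 0.219 for independent calls.

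The progesterone-induced list was lower in mutant P4 pools, with 6 of 23 lower and 0 higher (9 and 0 over the list alone), at a median of -0.191 (camera adjusted p = 5.05e-06, adjusted p = 0.164 with an estimated correlation). All 20 tested genes shared with the glucocorticoid response were lower, 3 called (5 over the list alone), at a median of -0.174 (camera adjusted p = 6.57e-05, adjusted p = 0.333 with an estimated correlation), among them Errfi1 (-0.83) and Dusp1 (-0.45). Immediate early genes were lower, with 2 of 23 called (6 over the list alone), at a median of -0.235 (camera adjusted p = 5.67e-05, adjusted p = 0.215 with an estimated correlation), with the nuclear receptor gene Nr4a3 at -0.83. Hox and Mullerian genes were higher, with Wnt7a the 1 call (3 over the list alone), at a median of 0.176 (camera adjusted p = 0.00343, adjusted p = 0.333 with an estimated correlation). In lists that were not called, the glycolysis genes Slc2a3 and Pfkfb3 (-0.60 and -0.47), the circadian genes Nfil3 and Npas2 (-0.92 and -0.72) and the estrogen-responsive Greb1 (-0.79) were lower. The cell cycle list (camera adjusted p = 0.882) and the adipocyte list (0.997) were not called. Median, mean and test differed in sign for the cell cycle, glycolysis, smooth muscle, adipocyte, EGF and BMP lists. The count of 187 became 113, 98 and 55 without wild-type P4 pool 1, 2 or 3, 92, 100 and 49 without mutant P4 pool 1, 2 or 3, and 116 without wild-type vehicle pool 1. Fkbp5 lost its call without any 1 of the 6 P4 pools, Cyp26a1 without pool 3 of either P4 group and Wnt7a without mutant P4 pool 3, while Atp6v0d2, Fst, Il13ra2, Cldn2, Wfdc15b, Scube2, Tac2, Ttr, Tspan8, Kctd14, Nr4a3 and Nfil3 kept theirs whichever pool was left out.

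**Figure D3:**
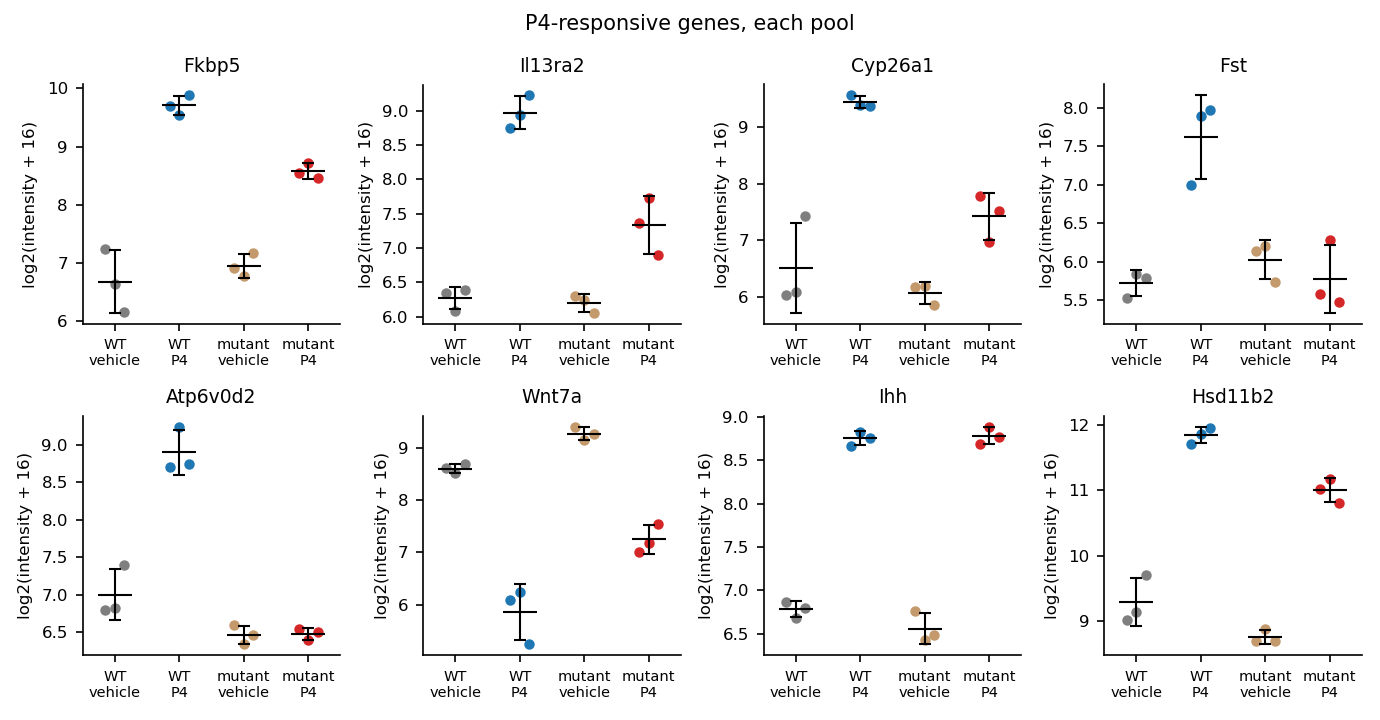
Values of 8 P4-responsive genes as log2(intensity + 16) in each pool, by group; dots are pools, the horizontal mark is the mean and the bars are the SD (n = 3). Atp6v0d2, Cyp26a1, Fst, Il13ra2 and Fkbp5 are lower in mutant than in wild-type P4 pools and Wnt7a is higher, while Ihh reaches a similar level in both.

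The last comparison tested whether the response to P4 itself differed between genotypes. The change with P4 was lower in mutants for Atp6v0d2 (log2 interaction -1.88, SE 0.241, adjusted p = 0.0237), Il13ra2 (-1.56), the retinol-binding gene Rbp7 (-1.51), Tac2 (-1.44), Aldh1a7 (-1.32, adjusted p = 0.00777), Wfdc15b (-1.25), the serine synthesis gene Phgdh (-1.09), Nr4a3 (-1.01), B3gnt7 (-0.94) and Pfkfb3 (-0.83), and higher for Ctsf (0.58). Atp6v0d2 went from 114.9 ± 32.9 to 468.9 ± 104 (SD, n = 3) with P4 in wild type and from 72.67 ± 7.65 to 73.51 ± 4.8 in mutants. Aldh1a7 went from 291.1 ± 25.6 to 602.4 ± 76.1 in wild type and from 595.1 ± 27.8 to 474.9 ± 38.8 in mutants. In limma 28 genes were called, 2 with a higher and 26 with a lower value of the interaction, 1 Riken clone in each direction among the largest. At an unadjusted p of 0.05 there were 1738. Fst (-2.15, adjusted p = 0.052), Fkbp5 (-1.40, adjusted p = 0.117) and Cyp26a1 (-1.58, adjusted p = 0.1) did not pass the test, so for these a difference between the P4 responses was not shown. Of the named genes, Aldh1a7 alone kept its call whichever pool was left out. The count became 7, 2 and 18 without wild-type vehicle pool 1, 2 or 3, and 5, 17 and 10 without wild-type P4 pool 1, 2 or 3. Without wild-type P4 pool 2 the balance turned, with 10 of the 17 higher and 7 lower. It became 8 and 2 without mutant vehicle pool 2 or 3, and 3 and 2 without mutant P4 pool 1 or 3. With the adipocyte covariate 3 genes were called, 2 of them among the 28, and all 28 kept their direction while the median SE rose from 0.131 to 0.16. Lower precision was not the only reason. Rbp7 shrank from -1.51 to -1.07 while its SE fell from 0.247 to 0.203. Pfkfb3 shrank from -0.83 to -0.65 at an SE of 0.131 and then 0.133. Il13ra2 (-1.82), Wfdc15b (-1.34) and Nr4a3 (-1.12) instead grew, and lost their calls as their SEs rose.

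Camera called 6 lists for the interaction. The P4 response was lower in mutants for the progesterone-induced list (median -0.172, 0 higher and 1 lower of 23, 6 lower over the list alone, adjusted p = 0.00235) and for genes shared with the glucocorticoid response (-0.22, 0 called of 20, 3 over the list alone, adjusted p = 0.000139). It was lower for the cell cycle list (-0.459, 0 called of 29, 4 over the list alone, adjusted p = 1.1e-07) and the adipocyte list (-1.52, 0 called of 8, 0 over the list alone, adjusted p = 0.00031), both of which differed in the vehicle pools. The cell cycle mean was 7.12 in wild-type vehicle pools and 7.51 to 7.59 in the other groups. Its rise with P4 in wild type, its vehicle difference and its interaction thus share the same low pools. The adipocyte mean was 10.4 in mutant vehicle pools and 8.78 to 8.89 elsewhere. Its fall with P4 in mutants, its vehicle difference and its interaction thus share those high pools. The Wnt pathway (0.184, adjusted p = 0.0117) and Hox and Mullerian lists (0.199, adjusted p = 0.0112) were higher, each with 0 calls. With an estimated correlation the adjusted p values were 0.333, 0.333, 0.578, 0.558, 0.215 and 0.333 in the same order. Over all 5 contrasts camera called 26 of 120 tests, of which 0 held with an estimated correlation. Fry, which does not compare a list with other genes, called 31, among them 15 of these 26. It lost 11, including the cell cycle (adjusted p = 0.0799) and adipocyte lists (0.0739) in vehicle pools. Signs differed between median, mean and test for the endothelial and BMP lists in this contrast, and for the steroid receptor, ion transport and cholesterol lists with P4 in mutants.

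**Figure D4:**
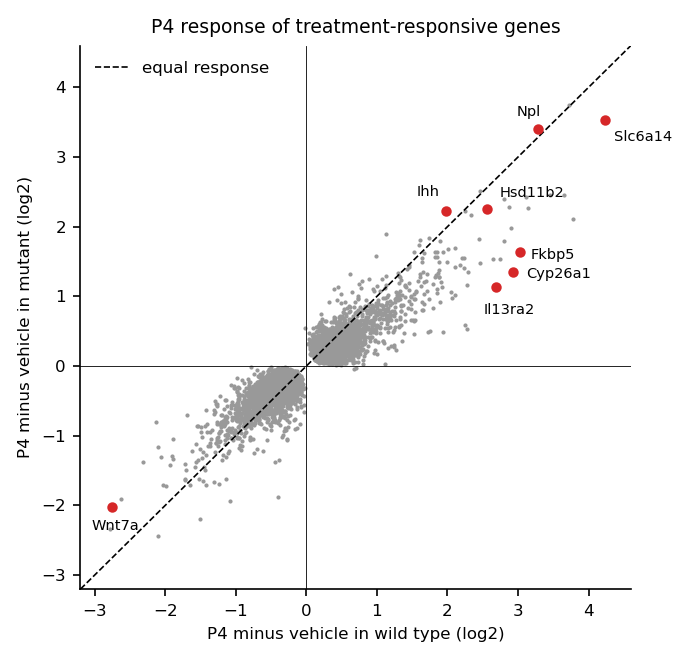
Log2 change with P4 in mutants (vertical axis) against wild type (horizontal axis) for 6047 genes chosen on treatment alone; each dot is a gene, and the dashed line marks equal responses. The response was smaller in mutants for 4185 of them (69.2%).

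Among 6047 genes that responded to treatment when genotype was ignored, the response was smaller in mutants for 4185 (69.2%). The 2685 raised genes had a median log2 change of 0.366 in wild type and 0.282 in mutants, and the 3362 lowered genes of -0.359 and -0.302. The median difference, signed by the direction of the response, was -0.0831 (exact permutation p = 0.055, two-sided, smallest possible 0.005), which did not pass the threshold. Regrouping the vehicle pools hardly moves a difference that lies in the P4 pools, so this p can stay well above the smallest possible. Whether the real difference lies in the P4 pools was not tested. A simulated difference of -0.3, placed in the P4 pools of independent genes, gave exact permutation p values up to 0.095. Simulated equal responses gave exact permutation p values down to 0.065. The missed threshold therefore does not argue against a weaker response in mutants, and a p of 0.055 does not show one. Genes chosen in wild type gave a median of -0.1475 (exact permutation p = 0.015) and genes chosen in mutants gave -0.02294 (exact permutation p = 0.6), and choosing genes in 1 genotype favours a larger response there. Without mutant vehicle pool 1 the median was -0.1003 (exact permutation p = 0.03).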

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

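The tests of dissected fat, of the epithelial share and of single pools below were chosen only after the patterns had been seen. The first group of results stands here because the P4 response differed between genotypes by a test of the difference itself. It held for 28 genes, though with a replicate block for only 4, 1 higher and 3 lower. In the named ones of the 28 the log2 interaction was 0.583 for Ctsf, -1.88 for Atp6v0d2, -1.56 for Il13ra2, -1.51 for Rbp7, -1.44 for Tac2 and -1.32 for Aldh1a7. It was -1.25 for Wfdc15b, -1.09 for Phgdh, -1.01 for Nr4a3, -0.938 for B3gnt7 and -0.834 for Pfkfb3. List medians were -0.172 for progesterone-induced genes, -0.22 for genes shared with the glucocorticoid response, -0.459 for cell cycle genes, -1.52 for adipocyte markers, 0.184 for the Wnt pathway and 0.199 for Hox and Mullerian genes. These 6 list calls rest on the preset correlation, and with an estimated correlation their adjusted p values were 0.333, 0.333, 0.578, 0.558, 0.215 and 0.333, so none was kept. Other splits of the pools were counted. Of 100 splits drawn from 200 that regroup genotypes within treatments, 3 gave at least 28 genes, the real one among them. The other 2 gave 74 and 40 genes. The highest keeps both genotype groups whole and exchanges them in the P4 pools, so it tests the sum of the genotype differences under the 2 treatments. Genes that differ in the same direction under both can pass it, as can genes that differ strongly under 1. This is a structure of these samples. The split with 40 genes puts wild-type P4 pools 2 and 3 together with mutant P4 pool 2. A mixed grouping thus gave more genes than the real one. The real count also fell to 2 without wild-type vehicle pool 2, so chance is not excluded.

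For the comparisons of 3 pools with 3, there are 10 splits, too few for a share under 0.05. The real split was the 1 with as many genes for P4 in wild type (5111, highest other 0), for P4 in mutants (3807, highest other 0), for genotype with vehicle (16, highest other 0) and for genotype with P4 (187, highest other 4).

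Adipocyte markers were higher in mutant vehicle pools. Dissected fat in differing amount would move these markers together from pool to pool within a group, and the median pairwise correlation of their residuals was 0.925, against a 95th percentile of 0.192 in 1000 random lists. Other lists of genes that vary together also exceeded random lists (interferon 0.789, cell cycle 0.784, smooth muscle 0.692, leukocyte 0.677), so this value does not point to fat in particular. Adipoq reached an intensity of 3700 ± 2490 (SD, n = 3) in mutant vehicle pools against 970.6 ± 486 in wild type, and Fabp4 8338 ± 3090 against 3018 ± 1310. Fat left on the uteri is a candidate source of this signal, and an effect of the mutant genotype cannot be told apart from it. The same holds for the fall of the list with P4 in mutants and for its interaction, which share these vehicle pools. Splits of the pools bear on chance only, and 3 pools against 3 give an exact permutation p of 0.1 at best, the value found. In the P4 pools no genotype difference was seen, with list means of 8.89 in mutants and 8.87 in wild type (camera adjusted p = 0.997).

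Cell cycle genes were higher in mutant vehicle pools at a median of 0.515. The rise of the list with P4 in wild type and its interaction share the wild-type vehicle pools with this difference, so they do not stand apart from it. The values argue against 1 low wild-type pool as the whole source, since the lowest median with 1 wild-type vehicle pool left out was 0.364 (pool 2). Without mutant vehicle pool 3 the median was 0.368, so single pools in both genotypes carried part of the difference. A larger share of epithelial cells, whose markers were higher by a median of 0.16, stays open, because the cell cycle mean less the epithelial mean was 0.287 higher in mutants (exact permutation p = 0.1, the least 3 pools against 3 can give), and its lowest mutant pool lay only 0.0692 above the highest wild-type pool, with a range of 0.191 within a group. The residuals of the list were correlated (median 0.784), its test did not hold with an estimated correlation, and an effect of the genotype on proliferation remains an open hypothesis, as does a larger share of another cell type that cycles, such as leukocytes, whose markers were higher in 23 of 29 (median 0.149, camera adjusted p = 0.0986).

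Probe sets outside the gene tests also carried a P4 response. Of 6077 such probe sets tested, 514 were higher with P4 in wild type and 460 lower, and 278 and 145 of these were so in both genotypes. The largest rise was 7.79 times, 36 rose at least 2-fold, and 1 was called for the interaction.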

How the results depend on the processing

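The covariate was chosen after the data had been seen, all other alternatives before. Lower Ncoa2 in mutant vehicle pools kept its call except with the mean of probe sets (-0.4512, adjusted p = 0.0526), over a range of adjusted p from 6.64e-07 to 0.0526, and with a replicate block it was 0.000501. Of 238 named calls, 177 held when any 1 pool was left out (194 to 218 calls per fit) and 224 held under both quantile normalization and median centring. All 26 list calls held under both scalings, and 20 held when any 1 pool was left out (23 to 36 calls per fit). Leaving out 1 pool gave 3944 to 5110 genes for P4 in wild type, 2674 to 3976 for P4 in mutants, 2 to 39 for genotype with vehicle, 49 to 170 for genotype with P4 and 2 to 23 for the interaction. A group left with 2 pools was assumed to vary like the others.

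For P4 in wild type the 5111 genes became 8494 with each probe set on its own, 3278 at an adjusted p under 0.01 and 1377 at 1.5-fold or more. For P4 in mutants the 3807 became 6051, 1873 and 837 under these settings and 1612 with the adipocyte covariate. With vehicle the 16 genes became 4 with quantile normalization, 6 with an added 1, 32 with an added 64, 3 without a filter, 6 with the 50th percentile as the filter, 3 with each probe set, 2 with the mean of probe sets, 37 with only the compared groups, 44 with array weights and 3 at 0.01. With P4 the 187 became 298 with an added 64, 99 without a filter, 28 with only the compared groups, 320 with a trended robust prior, 37 at 0.01 and 61 at 1.5-fold. The interaction's 28 became 10 with an added 1, 44 with an added 64, 6 without a filter, 10 with each probe set, 18 with the mean of probe sets, 52 with the trended prior, 47 with weights, 3 with the covariate and 2 at 0.01. With a replicate block the counts were 5018 and 3684 for P4, 2 and 119 for genotype with vehicle and P4, and 4 for the interaction.

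The 26 list calls became 48 with each probe set, 17 at 0.01 and 0 with an estimated correlation. The circadian list with P4 in wild type changed sign and passed with each probe set (adjusted p = 0.04978, up to 0.999 over its alternatives). The median signed response difference passed with genes called in wild type (-0.1475) and without mutant vehicle pool 1, in a range of -0.1003 to -0.06693 over left-out pools. The red blood cell list has no value with the stricter filter, which left none of its genes. A stricter threshold lowers a count by construction, and for the other settings the cause was not tested. Dim genes limit what can be seen, since the filter lay at an intensity of 21.1.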

Other observations

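The tests of the keratin pattern were chosen after it had been seen, and that of the genes beside Pgr before its result. P4 in mutants also changed genes of lists that camera did not call. Of 21 glycolysis genes 7 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.0986), with Slc2a3 3.19 and Pfkfb3 2.65 times higher. Of 15 Hox and Mullerian genes 6 rose and 2 fell (7 and 2 over the list alone, camera adjusted p = 0.201), with log2 changes of 0.90 in Hoxa10, 0.58 in Hoxa11 and 0.67 in Wnt4. Circadian genes rose in 6 and fell in 2 of 17 (7 and 2 over the list alone, camera adjusted p = 0.159), with Nfil3 and Npas2 both at 1.07 and Rora at -0.72. Wnt pathway genes rose in 5 and fell in 6 of 26 (6 and 10 over the list alone, camera adjusted p = 0.602), with Wnt11 at 1.84 and Fzd10 at -0.99. Of 18 ion and water transport genes 6 rose and 1 fell (camera adjusted p = 0.402), among them the sodium pump subunit gene Atp1b1 (2.50 times higher) and Fxyd4 (2.98). Estrogen-responsive genes rose in 5 and fell in 4 of 20 (camera adjusted p = 0.617), with the growth factor gene Igf1 at 1.17 and the cyclin gene Ccnd1 at -0.70.

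Of 8 tested basal-layer markers, 6 were lower in mutant than in wild-type vehicle pools at an unadjusted p of 0.05. Itgb4 (-0.04) and Itga6 (0.04) showed no such difference. Upper-layer markers were lower in 7 of 12 at that threshold, among them Krt13 (-2.73), Pkp1 (-2.38) and Calml3 (-1.47). The upper-layer keratin gene Krt10 (-0.09) was among those that were not. The lower basal-layer markers also differed between the wild-type P4 pools, where Col17a1 had intensities of 33.05, 136.3 and 16.52 and Krt15 of 201.9, 455.2 and 114.4. Of all 34 markers of stratified epithelium listed, 20 were tested. Of the 12 besides Krt5 that were lower, 11 followed the order of Krt5 over the 3 wild-type P4 pools, an order found in 19.4% of all genes (exact binomial p = 1.43e-07, one-sided, genes not independent). A stratified epithelium present in differing amount may underlie the differences. Genes that vary together for another reason would also share an order, so this result does not single it out. Cervical or vaginal tissue taken with the wild-type uteri would also bring upper-layer genes. Of these, 7 of 12 tested were lower, and 3 of the 6 with a mean log2 of at least 7 in wild-type vehicle pools. That level was set after the pattern had been seen, and the share depends on it. The counts decide nothing, and that source cannot be told apart from a genotype effect on basal cells within the uterus.

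Cre at the Pgr locus could bring along alleles of the strain in which it was made. Of 75 tested genes beside Pgr, 2 (2.67%) differed between genotypes in the same direction under both treatments at an unadjusted p of 0.05, against 184 of 13568 other genes (1.36%, Fisher's exact p = 0.273, two-sided). These were Cfap300, 3 genes away (0.587 with vehicle, 0.449 with P4), and Pdgfd, 14 genes away (-0.404 and -0.529). The count is too small to decide, and single genes near Pgr remain open to this reading.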
